A study of Shewanella oneidensis MR-1 with 8 samples.

How the data were processed

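The series compared wild-type (WT) Shewanella oneidensis MR-1, a bacterium that respires metals and many other electron acceptors, with a strain deleted for hnoC (SO_2540). There were 4 arrays per strain, and the labels call the replicates independent. Per the labels' protocols, 3 mL cultures stood without oxygen in 12-well plates in a mineral medium at 29 °C for 15 h. RNA was taken from 2.5 mL of each culture, and 100 ng of it was amplified into Cy3-labelled cRNA. Each sample was hybridised alone to an Agilent custom array in 1 colour.

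The values used were the intensity columns of the scanner output of each array, which per the file headers came from Agilent Feature Extraction 9.5.3.1. The processed signal in these files had already been corrected for background by that software, per the file headers. The deposited series value table holds log2 values of the same spots, with column medians between 5.35 and 5.38. Its rows were matched by spot number, and its Spearman correlation with background-subtracted intensity was 0.993 to 0.999 across spots. Its scale is log2 and its direction follows the signal, but its background method is not given in the sources used here, and it served only as an alternative. The submitters' processing notes name limma and no version.

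Each array held 15208 spots besides the 536 control spots, for 13180 probes and 4643 locus tags. The log2 of the processed signal was reduced by the array's own 75th percentile over spots other than controls. Spots marked as outliers were left out and the spots of a probe were averaged. A probe was kept if it was well above background on every array of at least 1 strain, which left 5502 probes. A gene's value was the median of its kept probes, and 2693 locus tags were tested while 1950 were too dim. No spot was saturated. Of all locus tags, 4263 matched the RefSeq table of assembly ASM14616v2, which was used only for names and for which genes lie beside each other. The build behind the array design is not given in the sources used here, so no coordinates are printed. Names of the hno genes other than hnoC come from knowledge of the study, and the RefSeq table calls hnoD (SO_2541) nosR.

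Strains were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on log2 values, with 2-sided tests and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Where a strain's arrays were all not well above background, the fold is a bound, written "at least". It sets the brighter strain's mean against the dimmer strain's mean of the lowest signal among probes well above background on each array, or the probe's own signal if higher. Gene lists were written before the data were examined, as were the processing alternatives and the main design. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 25 lists. Some lists, built from words in names, hold a few members of other function, and these were kept. Genes named are hnoC, the other hno genes, the genes within 2 tag numbers of each, up to 12 passing genes of largest rise and of largest fall, and up to 4 members of each list that was called. Other genes are said to have been chosen after their values were seen.

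The arrays lay on 2 slides, scanned separately. The second slide held WT replicate 3 and del_hnoC replicate 4, so slide could be added as a block. Each slide held equal numbers of both strains, so this left every log2 change as it was and altered its error only. Correlations between arrays across genes ran from 0.786 to 0.994, and no array was a copy of another. For arrays, the number of replicates limits the precision.

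Alternatives were quantile or median scaling, normexp background correction (offset 50) with each scaling, no filter or a stricter filter on dim probes, the mean or the brightest probe, eBayes with trend and robust settings, the series value table, slide as a block, replicate number as a block, each array left out, and other set tests. The fit was tested on data simulated for this comparison from the 2693 tested genes, with 200 genes changed, in 5 draws. Without a block it recovered 19.1% of genes changed by 1 on the log2 scale, 83.9% of those changed by 2 and 97.9% of those changed by 3. With slide as a block, on other data drawn with the slide effect and that fit's own errors, it recovered 79.7%, 99.4% and 100%. Benjamini-Hochberg adjustment is stricter where fewer genes change. These shares, from 200 changed genes, may therefore overstate recovery in the data, where 9 genes passed without a block. The data without a block held no slide effect, so the difference in recovery does not compare the fits on the same data. False calls were 4.57% and 5.55% of the calls, where data drawn from each fit's own model keep them near the set level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.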

Results

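Transcript levels were measured in 4 WT and 4 del_hnoC cultures of Shewanella oneidensis MR-1 grown without oxygen for 15 h. The comparison addresses which genes depend on HnoC, a response regulator of the signalling network around the nitric oxide sensor H-NOX. The 6 arrays of the first slide had 61.7% to 75.3% of their probes well above background. On the second slide WT replicate 3 had 38.0% and del_hnoC replicate 4 had 39.9%. The 75th percentile of the signal was 98.6 to 126 units on the first slide, and 44.2 and 25.8 on those 2 arrays.

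hnoC itself was well above background on all 4 WT arrays and on none of the 4 del_hnoC arrays. Its WT level was 1.03 ± 0.41 (SD, n = 4) on the log2 scale relative to the 75th percentile of each array. It was at least 16.6-fold lower in del_hnoC, with a limma adjusted p of 9.15e-04 and an adjusted p of 1.59e-04 with slide as a block. All 3 of its probes were lower. The fitted log2 change, which depends on the scanner's floor, was −6.35, and it was −7.08 on the first slide and −4.15 on the second. The change was smaller than the bound with the series value table, at −3.55, and with normexp and quantile scaling, at −1.95 (SE 0.16), where it passed (adjusted p 6.74e-04 and 0.0025). It was −1.96 with normexp and the 75th percentile, where it did not pass (adjusted p 0.163).

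Of the H-NOX network genes, all 3 that could be tested rose in del_hnoC. hnoD (SO_2541), a response regulator, rose 8.70-fold, from 1.92 ± 0.80 to 5.04 ± 0.64 (SD, n = 4, log2 scale). hnoB (SO_2539), a phosphodiesterase that degrades the second messenger cyclic di-GMP, rose 8.61-fold, from −0.93 ± 0.20 to 2.18 ± 0.64. hnoX (SO_2144), the nitric oxide sensor itself, rose 3.19-fold, from −1.41 ± 0.32 to 0.26 ± 0.18. The log2 changes were 3.12 (SE 0.45) for hnoD, 3.11 (SE 0.34) for hnoB and 1.67 (SE 0.25) for hnoX, with limma adjusted p of 0.0176, 0.0039 and 0.0211. With slide as a block the adjusted p were 4.82e-04, 1.59e-04 and 0.0022. The changes on the first and the second slide were 3.09 and 3.21 for hnoD, 3.33 and 2.45 for hnoB, and 1.74 and 1.49 for hnoX. All 3 also passed when adjusted over the list alone. The list as a whole was higher by camera, with an adjusted p of 1.07e-07, and an adjusted p of 0.0194 with an estimated correlation. By the set test fry it was higher too (adjusted p 1.03e-04), but it did not pass by fry in either direction (adjusted p 0.0711). The histidine kinase gene hnoK (SO_2145) was too dim to be tested. The call of hnoX was lost without WT replicate 1, 2 or 4 or del_hnoC replicate 1, 2 or 3, at adjusted p of 0.0825 to 0.148. It was also lost with the array median (0.0521), with no filter (0.0852) and with the brightest probe (0.0571). That of hnoD was lost without WT replicate 4 or del_hnoC replicate 1, 2 or 3, at 0.0801 to 0.101.

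Genes next to the hno genes on both sides of hnoC rose as well. SO_2538, a response regulator gene beside hnoB, rose 5.98-fold. On the other side, beyond hnoD, SO_2542 (a signalling protein with a FIST domain) rose 6.48-fold, SO_2543 (a sensor histidine kinase) 5.06-fold and SO_2544 (a hybrid sensor histidine kinase) 5.05-fold. Their log2 changes were 2.58 (SE 0.37), 2.70 (SE 0.29), 2.34 (SE 0.29) and 2.34 (SE 0.26), with limma adjusted p of 0.0176, 0.0039, 0.0067 and 0.0039. With slide as a block these were 0.0057, 1.59e-04, 7.75e-04 and 6.43e-04. On the first slide the 4 log2 changes were 3.06, 2.66, 2.17 and 2.27, and on the second 1.12, 2.81, 2.84 and 2.52. SO_2543 and SO_2544 were not well above background on WT replicate 3, the only WT array of the second slide. Their values there, −2.72 and −2.53, lay below the array's lowest well-above signal of −1.27. Their second-slide changes are therefore not measured sizes. Normexp with the 75th percentile gave 1.44, 1.76, 0.97 and 0.97, and normexp with quantile scaling 1.32, 1.80, 0.92 and 0.93. SO_2544 rests on 1 kept probe of 3, and without the filter its log2 change was 1.76 with an adjusted p of 0.930. The call of SO_2538 was lost without WT replicate 1, 2 or 4 or del_hnoC replicate 1, 2 or 3, at adjusted p of 0.0755 to 0.101.

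The neighbourhood of hnoC, taken as the genes within 10 tag numbers outside the hno genes, had 7 tested members, of which 4 rose and 3 did not pass. Adjusted over the list alone, 5 passed. With slide as a block 5 rose, the 4 and cheY_4 (SO_2547, chosen after its values were seen), whose adjusted p went from 0.511 to 0.0108. Adjusted over the list alone with that block, fadE (SO_2536, chosen likewise) was also lower, at −0.51. The list was higher by camera with an adjusted p of 7.32e-07, and an adjusted p of 0.0194 with an estimated correlation. Its mean difference was 1.70 on the first slide and 1.52 on the second. Beside hnoX, the amino acid antiporter gene aspT (SO_2143) had a log2 change of 0.64 (SE 0.73, adjusted p 0.778), while SO_2146, recD (SO_2147) and, beside SO_2538, SO_2537 were too dim to be tested.

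**Figure D1:**
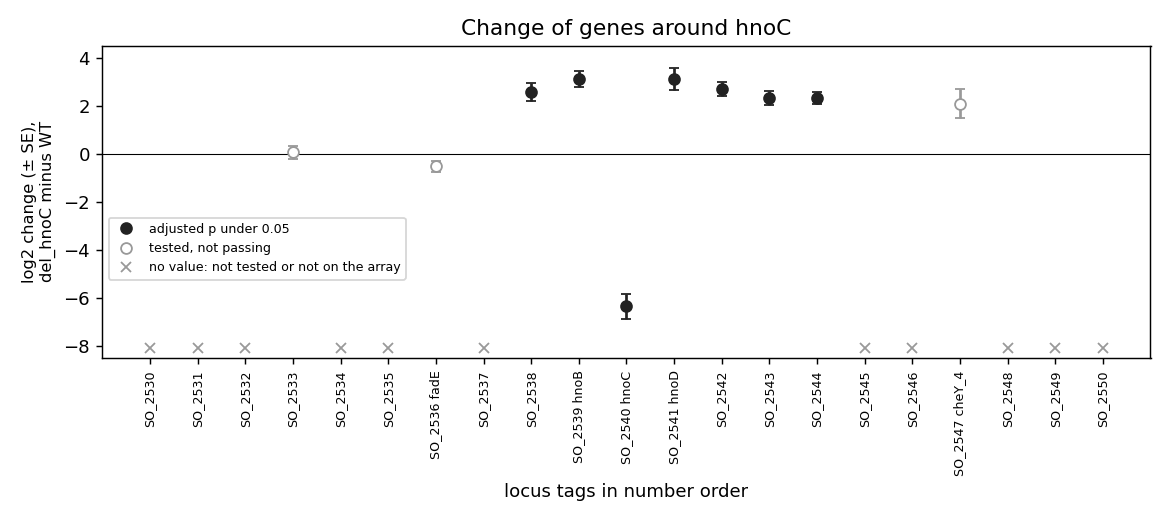
Log2 change of del_hnoC against WT, with its standard error (n = 4 arrays per strain), for the locus tags around hnoC in number order; filled points passed at an adjusted p under 0.05 and crosses mark tags with no value. hnoC lies at −6.35 between genes at 2.34 to 3.12.

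Away from the hno genes, only SO_1695 passed among the genes tested without a block. SO_1695 encodes a diguanylate cyclase, an enzyme that makes cyclic di-GMP, with a PAS sensory domain. It was well above background on all 4 del_hnoC arrays and on none of the WT arrays, and was at least 2.50-fold higher in del_hnoC (limma adjusted p 0.0060, and 2.14e-04 with slide as a block). Its call was lost with normexp and quantile scaling, where the other 7 higher genes passed, at a log2 change of 0.64 (SE 0.12, adjusted p 0.127), below the bound. The call was also lost with normexp and the 75th percentile, at 0.71 (adjusted p 0.998). SO_1695 rests on 1 kept probe of 3, at a log2 change of 3.42, and the 2 not kept were at 3.69 and 2.75. With no filter, which uses all 3, it passed at 3.24 (adjusted p 0.0256). Its fitted log2 change, which depends on the scanner's floor, was 3.78 on the first slide and 2.33 on the second. In total 9 genes passed, 8 higher and 1 lower, and all 9 differed by at least 2-fold. With slide as a block 11 passed, 10 higher and 1 lower. An unadjusted limma p under 0.05 was found for 251 genes without a block and 747 with slide as a block. Whether these are weak changes in many genes or errors set too low by the block was not tested. List members that pass only with that block, adjusted over a list alone, are therefore not set apart from other genes. That adjustment also does not count the number of lists. No del_hnoC value of the 9 genes lay within the range of WT. Such separation was found for 226 of the 2693 tested genes, or 8.39%, against 2.86% by chance. The filter, which keeps probes bright in either strain, can favour separated genes, and all genes share the same arrays. The excess therefore does not count changed genes. With normexp background correction and the 75th percentile no gene passed in limma, and 104 had an unadjusted p under 0.05.

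**Figure D2:**
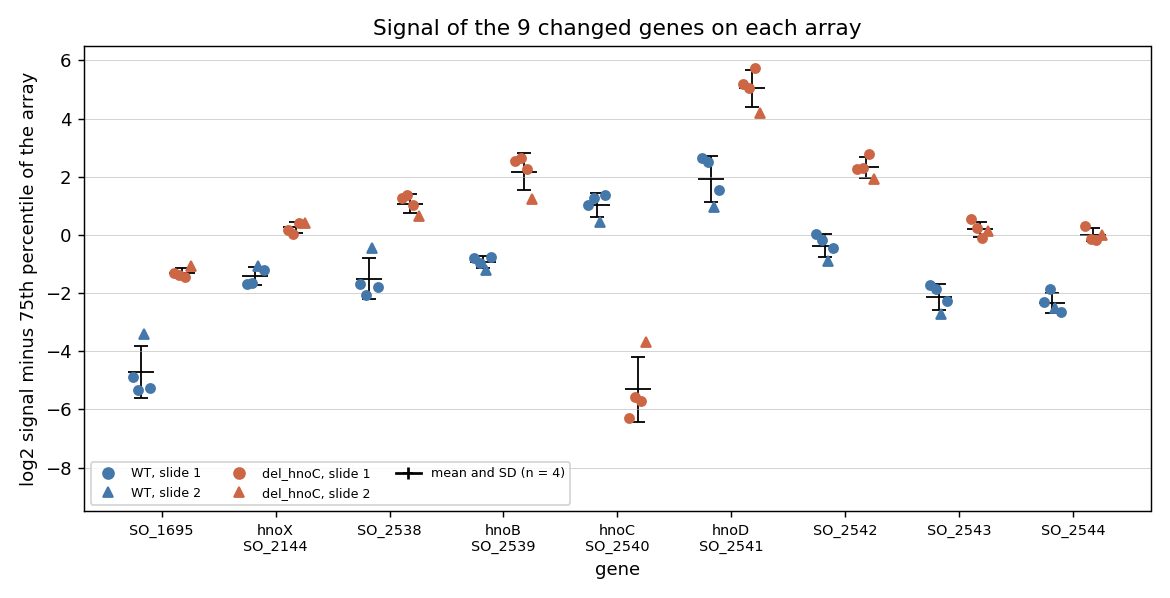
Log2 signal relative to the 75th percentile of each array for the 9 changed genes, with circles for first-slide and triangles for second-slide arrays and bars for the mean and SD (n = 4). hnoC was at 0.46 to 1.36 in WT, and the other 8 genes were higher on every del_hnoC array than on any WT array.

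Cyclic di-GMP enzymes changed in 2 of 45 tested genes, hnoB and SO_1695, both higher, and the list did not stand apart (camera adjusted p 0.457). Adjusted over the list alone with slide as a block, pdeB (SO_0437) and SO_2127 were also higher and SO_2862 lower, all 3 chosen after their values were seen. Among histidine kinases and response regulators outside the hno genes, 3 of 32 rose and 29 did not pass. These were SO_2538, SO_2543 and SO_2544, which are also neighbours of hnoC. The number was 4 with slide as a block, which added cheY_4, and 9 when also adjusted over the list alone. The list was higher by camera (adjusted p 1.65e-04, and 6.68e-04 with slide as a block), with an adjusted p of 0.325 with an estimated correlation. Its mean difference was 0.62 on the first slide and 0.67 on the second.

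Chaperone and protease genes had negative log2 changes in all 10 tested members, none of which passed. The median was −1.01. Among them groES (SO_0703), a co-chaperonin, had a log2 change of −1.37 (SE 0.71, adjusted p 0.550), and dnaK (SO_1126), an Hsp70 chaperone, −1.26 (SE 0.74, adjusted p 0.581). That of groES was −0.70 without WT replicate 4, and that of dnaK −0.55 without del_hnoC replicate 4. The list was lower by camera (adjusted p 2.47e-05, and 1.59e-04 with slide as a block), with an adjusted p of 0.467 with an estimated correlation. The list mean was 3.89 ± 0.80 in WT and 2.94 ± 0.64 in del_hnoC (SD, n = 4), and the difference was −0.76 on the first slide and −1.53 on the second.

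Mobile elements had no passing member over all genes tested, and with slide as a block adjusted over the list alone 12 prophage genes were lower and 1, SO_0688 (chosen after its values were seen), higher. Genes of the Mu and lambda prophages had a median log2 change of −0.23 over 75 tested genes, lower by camera (adjusted p 1.65e-04, 4.16e-05 with slide as a block), with an adjusted p of 0.0463 with an estimated correlation. It did not pass by fry (adjusted p 0.0790, and 0.324 in either direction), and the exact permutation p of the list means was 0.114 (2-sided, n = 4 each). The mean difference was −0.20 on the first slide and −0.19 on the second. Transposase genes had a median of 0.39 over 154 tested, higher by camera (adjusted p 1.65e-04, 1.05e-05 with slide as a block), with an adjusted p of 0.732 with an estimated correlation. Their mean difference was 0.22 on the first slide and 0.75 on the second, and without del_hnoC replicate 4 the camera adjusted p was 0.987. Their probes can hybridise to several copies. The 2 members of largest change in both lists were tnpA_MuSo2b (SO_2655), at 1.59 (SE 0.83, adjusted p 0.550), and SO_2036, at 1.26 (SE 0.73, adjusted p 0.581), which shares a probe sequence with another gene. Both rest on del_hnoC replicate 4, without which they were at 0.44 and 0.42. They were at 0.36 and 0.61 on the first slide and 5.30 and 3.22 on the second. Without WT replicate 3 the filter on dim probes kept a different set of probes for tnpA_MuSo2b, which was then at −0.14.

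Respiratory genes did not pass in any list, and no such list was called. None passed of 6 Mtr metal reduction genes (median log2 change 0.42), 23 alternative anaerobic reductase genes, 5 terminal oxidase genes, 28 c-type cytochrome genes, and 22 hydrogenase and formate dehydrogenase genes. The camera adjusted p of these lists were 0.258, 0.461, 0.258, 0.654 and 0.642 in that order. omcA, an outer membrane decahaem cytochrome, had a log2 change of 0.71 and mtrC, its partner in metal reduction, 0.51, with adjusted p of 0.537 and 0.550. With slide as a block adjusted over each list alone, omcA and SO_4142, a cytochrome, were higher. In the reductase list napA and napD were lower, as was psrA (SO_2493), which encodes a fatty acid degradation regulator and not a reductase. These genes and mtrC were chosen after their values were seen. The 3 tested nitrogen oxide stress genes had none passing (camera adjusted p 0.610).

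Surface and motility genes likewise had none passing over all genes tested without a block. Only 1 chemotaxis gene, cheY_4, passed with slide as a block. Adjusted over the list alone with that block, 9 pilus genes were higher and 1, pilV, lower, and cheW_2 joined cheY_4 among 2 higher chemotaxis genes. As that block gave 747 of the 2693 tested genes an unadjusted limma p under 0.05, these counts do not set the lists apart. The camera adjusted p was 0.0821 for 6 biofilm matrix genes, 2 of which were higher when adjusted over the list alone, 0.552 for 31 type IV and MSHA pilus genes, 0.654 for 55 flagellum genes and 0.552 for 35 chemotaxis genes. Growth and metabolism lists also had no passing gene. Adjusted over each list alone with slide as a block, icd and alcC were higher and feoA, hisG and leuC lower, all chosen, as were pilV and cheW_2, after their values were seen. The camera adjusted p was 0.654 for 57 ribosomal protein genes, 0.642 for 9 ATP synthase genes, 0.654 for 11 TCA cycle genes, 0.258 for 9 lactate and pyruvate genes, 0.325 for 15 sulfate assimilation genes, 0.654 for 24 iron and haem uptake genes, 0.258 for 11 amino acid biosynthesis genes and 0.709 for 6 DNA repair genes. For c-type cytochromes and ribosomal proteins the median was above 0 and camera, which compares with all other genes, pointed down. For DNA repair the median was below 0 and the mean above it.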

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

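Of the tests in this part, the count over splits of the arrays without a block and that of pairs of arrays left out were set before their results were seen, and the others were chosen or changed after. The largest pattern was the loss of hnoC with higher levels of 6 genes beside it and of hnoX and SO_1695 elsewhere. Of 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 9 genes, the real one, and the highest other gave 1. This argues against a chance division of the arrays but cannot exclude it, as 35 splits are few. Every other split also put both strains in each group, which widens the spread of the changed genes. The same count with slide as a block was 1 of 35, where the real split gave 11 genes and the highest other gave 1. An effect of the deletion on adjacent transcription is argued against for hnoX and SO_1695 mainly by their distance from hnoC in tag number. The genes between were not likely to carry such an effect that far, so their levels add little. The tested genes between hnoX and SO_2538 had a median log2 change of 0.016 (186 genes, 0 passing) and those between SO_1695 and hnoX one of 0.054 (211 genes, 0 passing), against 1.67 for hnoX. For the 6 genes beside hnoC, chosen because they passed, the median rise exceeded that of hnoX by 0.96 (SE 0.31). The difference was at least 0.75 over 6 scaling and background alternatives, as an added effect on adjacent transcription would give. The SE takes the genes as independent, though all were measured on the same arrays. The comparison rests on hnoX alone. The other distant gene, SO_1695, had a fitted rise of 3.42, above the 2.34 to 3.12 of the 6 genes. Being dim in WT, SO_1695 was bounded only at 2.50-fold or more, so it cannot decide. Promoters can also differ in their response, so loss of HnoC alone stays open too, and no complemented strain was analysed here. Scaling and background correction are argued against for the 7 higher genes other than SO_1695, whose smallest log2 change over 6 alternatives was 0.81. With normexp and the 75th percentile their calls ended, and the changes shrank: hnoB from 3.11 (SE 0.34) to 2.02 (SE 0.37), hnoX from 1.67 (SE 0.25) to 0.84 (SE 0.17), hnoD from 3.12 (SE 0.45) to 2.59 (SE 0.65), SO_2538 from 2.58 to 1.44, SO_2542 from 2.70 to 1.76, and SO_2543 and SO_2544 each from 2.34 to 0.97. For SO_1695, dim in WT, the smallest was 0.64 (SE 0.12), with normexp and quantile scaling, and it was 0.71 (SE 0.24) with normexp and the 75th percentile. Its call was lost under both (adjusted p 0.127 and 0.998), the only higher gene lost with the former, so scaling or background correction stays open as the source of its call and its size. This test was first set, before its result was seen, on all 8 higher genes with a bound of 0.5, and was divided and made to count the SE afterwards.

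On the 6 first-slide arrays 14 genes passed, against 9 on all 8. Measured there but too dim to test with the second slide were cheC (SO_2546), at a log2 change of 2.22, SO_4683, at −1.46, and hnoK (SO_2145), SO_2545 and SO_3800, all with limma adjusted p under 0.05. The last 3 were well above background on 3 of 3 del_hnoC arrays and 0 of 3 WT arrays of that slide, with 1 probe each, and were at least 2.41-fold, 1.68-fold and 1.18-fold higher. With no filter and slide as a block, yfjY (SO_1455) also passed, well above background on 2 of 4 del_hnoC arrays and 0 of 4 WT arrays, so no fold is given. All 5 additional genes of the first slide lacked a passing probe with all 8 arrays, which goes with low signal of the second slide. It replaced a test by the ratio of second-slide to first-slide change over the 14 genes (median 0.505), which choosing genes on the first slide lowers by itself. Leaving out any WT and del_hnoC array does not account for it, since 0 of the other 15 pairs gave as many genes and the highest gave 9. Whether these cultures also differed biologically was not tested.

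The chaperone set was lower in del_hnoC by camera at the preset correlation and not with an estimated correlation (adjusted p 0.467), and no member passed. Its mean ranged over 1.71 on the log2 scale among the WT arrays and 1.48 among the del_hnoC arrays, and the strains differed by −0.95. WT replicate 4 carried the WT range, and without it that range was 0.25, the del_hnoC range 1.48 and the difference −0.55. With each array left out in turn the larger range was at least 1.42 times the difference, so cultures that differ in chaperone level whatever the strain could give it. The first slide alone also held a difference, −0.76, or 0.798 of that over all arrays, so the dim second slide was not its only source. Without WT replicate 4, a first-slide array, the first-slide difference was 0.372 of that over the remaining arrays. How much the second slide added therefore stays open. An effect of the deletion stays open, as the strains' list means had an exact permutation p of 0.114 (2-sided, n = 4 each).

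Some arrays lay far from the rest of their group. The 75th percentile of the signal was 44.2 units for WT replicate 3 and 113 to 124 for the other WT arrays. tnpA_MuSo2b (SO_2655) was at 1.99 in del_hnoC replicate 4 and at −1.95 to −1.92 in the other del_hnoC arrays, and SO_2036 at 0.60 against −2.91 to −2.46. These are 3 of 32 groups examined, where chance gives about 1 in 20, or 1.6.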

How the results depend on the processing

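First-slide arrays alone, the 75th percentile over probes well above background on all 8 arrays, and slide as a block with no filter were chosen after seeing the data. The 9 genes were the same under quantile scaling, the mean of probes, trend and robust eBayes and the series value table. Normexp with the 75th percentile gave 0 genes, 0 of at least 2-fold, 0 H-NOX network genes and a log2 change of hnoC of −1.96 (limma adjusted p 0.163), with 104 genes at an unadjusted p under 0.05. Normexp with quantile scaling, at the same offset, gave 8 genes, without SO_1695, 5 of at least 2-fold, with smaller errors for all 8 higher genes, so the offset alone does not account for it. Probes well above background on all 8 arrays gave 5 genes, 5 of at least 2-fold, and no value for hnoC, because fewer genes were tested. The first slide alone gave 14 genes, 14 of at least 2-fold. Leaving out each array gave 6 to 11 genes, 6 to 11 of at least 2-fold, 1 to 4 H-NOX network genes, −6.89 to −6.02 for hnoC and 6 to 7 lists. The 6 genes came without WT replicate 4 or del_hnoC replicate 1, 2 or 3, and each of these left 1 H-NOX network gene. Without WT replicate 3 there were 9 and 3, without del_hnoC replicate 4 11 and 4, and the cause was not tested. Against 6 lists called, camera with an estimated correlation called 3, fry 3 and fry in either direction 3, the last including cyclic di-GMP enzymes (adjusted p 0.0044). The log2 change of tnpA_MuSo2b ran from −0.14 without WT replicate 3 to 1.92 without del_hnoC replicate 1. The filter on dim probes was applied again in each of these fits, and the negative value came with a changed set of probes. On the 1 probe kept with all 8 arrays, each del_hnoC value lay above each WT value. Leaving out WT replicate 3 alone therefore does not reverse that probe's change. Whether replicate numbers pair the samples could not be told from all same-number pairs together, as some of them cross slides. Of 4 same-number pairs 2 correlated over 0.1 (range −0.587 to 0.497), and 2 of 8 samples correlated best with their own number. The 2 pairs sharing a slide were at 0.160 and 0.497. The 2 across slides, which the replicate block also joins, were at −0.325 and −0.587. Pairs of different number on the first slide were also positive, at 0.141 to 0.558, a range that holds both same-number values there. No pairing by number was therefore seen within that slide, on few pairs. The replicate block gave 2 genes, 2 of at least 2-fold, both lower: hnoC, at −6.35 (adjusted p 0.0086), and recG (SO_4364, chosen after its values were seen), which the main comparison did not call. All 8 higher calls, with 0 of the H-NOX network genes left, were lost at unchanged log2 changes (hnoB 3.11, adjusted p 0.0752). Signal over background limits what could be tested, with 1950 locus tags too dim.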

Other observations

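All gene sets and genes in this part were chosen after their values were seen. In the biofilm adhesin locus 1 gene was among the highest that did not pass. SO_4317, a large calcium-binding surface protein, had a log2 change of 2.09 (SE 0.40, 4.26-fold, limma adjusted p 0.127, and 0.0534 with slide as a block). It was higher on all 4 del_hnoC arrays than on any WT array, at 3.13 ± 0.44 against 1.05 ± 0.76 (SD, n = 4), and by 2.005 on the first slide and 2.34 on the second. Its neighbour SO_4322, a periplasmic protein, was at 0.85 (SE 0.27, adjusted p 0.531). aggA (SO_4320), the outer membrane part of a type I secretion system, was at 0.42 (SE 0.67, adjusted p 0.849). SO_4323 was at 0.37 (SE 0.45) and SO_4321 at 0.16 (SE 0.54), with adjusted p of 0.793 and 0.928. The biofilm matrix list was called on the first slide alone, with a camera adjusted p of 0.0486. On all 8 arrays the adjusted p was 0.363 by camera with an estimated correlation and 0.108 by fry, and the list means had an exact permutation p of 0.0571 (2-sided, n = 4 each, 0.105 adjusted).

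Beyond the raised genes beside hnoC, 1 more passed over all genes tested only with slide as a block. Adjusted over the hnoC neighbourhood alone, it also passed without the block. cheY_4 (SO_2547), a chemotaxis response regulator, had a log2 change of 2.10 and an adjusted p of 0.511, which became 0.0108 with slide as a block, and it was 2.14 on the first slide, where it did not pass (adjusted p 0.0547), and 1.98 on the second. SO_0391, a conserved hypothetical protein, also passed only with that block, at least 1.39-fold higher (adjusted p 0.0191, and 0.0657 on the first slide). It rests on 1 kept probe of 3, and with the block and no filter it did not pass (adjusted p 0.380). In that setting SO_0823, a membrane peptidase, passed at 1.34 (adjusted p 0.0193).

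Within the prophage list the elements had mean differences of both signs, and the difference between elements was not tested. LambdaSo genes had the lower levels in del_hnoC, with 32 of 40 negative and a list mean of −0.36 in WT and −0.72 in del_hnoC. All 4 del_hnoC means lay below all 4 WT means (exact permutation p 0.0286, 2-sided, n = 4 each, the smallest possible, and 0.0629 adjusted over 11 sets). camera with an estimated correlation gave p of 0.0011, and 0.0063 with slide as a block, and the difference was −0.34 on the first slide and −0.44 on the second. MuSo1 genes differed by 0.24 over 9 genes (exact permutation p 0.0286, n = 4 each) and MuSo2 genes by −0.26 over 14 (0.314). No single prophage gene passed over all genes tested, and with slide as a block adjusted over the set alone 13 LambdaSo genes passed.

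All 100 tested tRNA genes had positive log2 changes, with a median of 0.41, or 0.35 under quantile scaling. The strains' means did not separate (exact permutation p 0.143, n = 4 each), and camera with an estimated correlation gave p of 0.202. No tRNA gene passed over all genes tested, and with slide as a block adjusted over the set alone 5 passed.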
